A study of Mus musculus with 17 samples.

How the data were processed

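Spinal cords of En1-Cre; Rosa.lsl.YFP mice (V1) and Ptf1a-Cre; Rosa.lsl.YFP mice (dI4) at E12.5, P0 and P5 were dissociated, and YFP-labelled interneurons were sorted by FACS, per the series' design text. RNA was isolated with the Absolutely RNA Nanoprep Kit, 1 to 5 ng was amplified with the Ovation Pico WTA System and labelled with the Encore Biotin Module, and Affymetrix mouse expression arrays were hybridized, per the labels and the design text. There were 17 arrays, 3 per class and age except 2 for dI4 at P5. How many animals or litters went into each array is not given in the sources used here.

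The deposited value table holds log2 expression for 45101 probe sets on the 17 arrays, background corrected and normalized by the authors. The submitters' processing notes name Partek 6.6, RMA and GCRMA, without the role or order of each. From the values, arrays of 1 age had close distributions and the ages differed, so the ages look normalized separately by the authors. Array medians lay between 3.12 and 3.23 at E12.5, between 5.32 and 5.56 at P0, and between 4.90 and 5.30 at P5. At P0 and P5 every V1 median lay below every dI4 median. Per the file headers, a second table by the authors holds the same log2 values (identical in all 766717 cells), gene symbols and, for each age, a fold score and a p-value. The fold score deposited by the authors is the signed linear fold of V1 over dI4, with the inverse written as a negative number where dI4 is higher. The p-value deposited by the authors is unadjusted, and from the values it matches an equal-variance test between the 2 classes within each age. Its test is not given in the sources used here, and the authors' fold and p-value columns were set beside the values computed here and entered no test.

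Symbols came from the authors' table, with the gene symbol updated by Entrez gene identifier from a GRCm38.p6 gene table. Of the probe sets, 64 were controls, 5812 had no symbol, 1399 named several genes and 37826 named 1 gene. The identifier of 34668 of the latter was found in the gene table, and 3821 symbols were updated. Each of the 20678 genes with such a probe set was represented by 1 probe set, the one with the highest mean over all 17 arrays, after those marked by the manufacturer as cross-hybridizing were set aside where the gene had another. A gene was tested if its probe set exceeded the array's median over all probe sets on at least 2 of the 17 arrays, which left 12899 genes. Precision rests on signal over background. As a measure of background the 12 bacterial control probe sets were used. Both classes lay at their level for 1523 tested genes at E12.5, 132 at P0 and 159 at P5. Of the genes called higher in V1, dI4 lay at that level for 37, 13 and 42, and of those called lower, V1 did for 5, 43 and 46.

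Group means were fitted to the log2 values of all groups together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes; 10 residual and 2.21 prior degrees of freedom). V1 replicates 1 and 3 at P0 entered as their mean, counted once. This choice was made after the arrays were compared, and entering them separately was run as an alternative. Contrasts were V1 minus dI4 at each age, the mean of these 3, and their change from E12.5 to P0 and from P0 to P5. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes were called at an adjusted p under 0.05. Changes between ages within 1 class had been planned and were not tested, because separate normalization of the ages would enter them directly. Separate normalization can also enter the changes in the V1 minus dI4 difference, because the ages differ in scale. Upper quartiles lay between 6.85 and 6.98 at E12.5, between 9.27 and 9.34 at P0, and between 9.16 and 9.25 at P5. Whether arrays with the same replicate number deviate together was checked from the values, and they were treated as unpaired.

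There were 26 gene lists, and those with at least 3 tested members, 21 at each age, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. With the preset correlation 11 lists were called at E12.5, 11 at P0 and 10 at P5, and with an estimated correlation 2, 2 and 1. Counts of called members are over all tested genes, and "adjusted over the list alone" gives the count when only the list's members were adjusted together. The list of V1 subset transcription factors came from factors picked in earlier work on these samples. Medians within 0.1 of 0 without a camera call (6 lists at E12.5 and 3 at P0) are given only as this count. Membership of 4 families, defined by patterns of the gene symbol, among genes called higher and among genes called lower at each age was tested with Fisher's exact test, two-sided, adjusted over the 24 tests. Genes are not independent replicates in that test.

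The text names En1 and Ptf1a, then for each age the 8 genes called higher and the 8 called lower with the largest log2 difference among genes whose V1 and dI4 arrays did not overlap. For the mean over ages it names 5 in each direction, with no overlap at any age, and for each change between ages the 3 highest and 3 lowest called genes. From each list up to 4 called members and up to 2 uncalled members of the highest expression could be named, and from each family up to 4 called members per direction at P0. Some genes that meet the rule are not named here. Clone and prediction names were passed over: 1 among the highest at E12.5, 1 among the lowest at P0 and 1 among the highest at P5. The groups, contrasts, thresholds, lists, families, naming rule and the alternatives not marked below as added were fixed before the data were examined.

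Alternatives changed 1 choice at a time: all probe sets tested (23801), the mean of a gene's probe sets, no filter on dim probe sets, a filter at the upper quartile (8084 genes), a further quantile normalization, median centring, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, at least a 2-fold difference, an adjusted p under 0.01, and leaving out each array in turn. Where this left 1 sample in a group, it was assumed to vary like the other groups. Added after seeing the data were V1 replicates 1 and 3 at P0 entered separately, dI4 replicate 2 at E12.5 and dI4 replicate 3 at P0 left out together, and the V1 arrays at P5 left out of the shared spread. Splits of the same arrays into other groups were also fitted, 10 within each age and 100 drawn of 2000 for the mean over ages.

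The fit was tested on simulated data in which each gene had its measured spread, the same in all groups. Of the genes, 100 were changed by a log2 difference of 1 and 100 by 2. It recovered 61% of the smaller changes at E12.5, 49% at P0 and 49% at P5, and 92%, 82% and 86% of the larger. False calls made up 4.4%, 6.4% and 5.6% of all calls. In the data the groups varied unequally. The SD of the difference between replicates 1 and 2 was 0.90 for V1 at P5 and 0.31 for dI4 at P0. Far more genes were also called than the simulation changed, so these shares need not hold for the real fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.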

Results

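Gene expression was measured on 17 microarrays of RNA from 2 classes of inhibitory interneuron sorted from mouse spinal cord. V1 interneurons, which arise in the ventral cord and express En1 as they leave the cell cycle, were marked by En1-Cre and a YFP reporter. The dI4 and late-born dILA interneurons of the dorsal horn, called dI4 here, were marked by Ptf1a-Cre and the same reporter. Each class was collected at embryonic day E12.5, at birth (P0) and 5 days later (P5). There were 3 arrays labelled as biological replicates in each group except dI4 at P5, which had 2. The p-values given for single genes measure variation between these labelled replicates, and the arrays' number limits the precision of every value. Those of camera set the genes of a list against the other tested genes, and those of Fisher's exact test count genes. Neither of these measures variation between replicates alone.

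Values were log2 expression per probe set, and 12899 genes were tested. V1 replicates 1 and 3 at P0 had a correlation of 0.999 across genes, and 16 genes differed 2-fold between them, against at least 157 in every other pair of replicates. They differed by far less than any other pair of replicates and were counted as 1 sample, so V1 at P0 enters with n = 2. The lowest correlation within a group was 0.953, between V1 replicates 1 and 2 at P5, followed by 0.956 for V1 replicates 1 and 3 and 0.964 for 2 and 3. Over all probe sets these pairs held 2323, 3024 and 2897 identical values, and the dI4 replicates at P5 held 1348. No pair at E12.5 or P0 held more than 17, and the cause was not tested. The 12 bacterial control probe sets, whose targets mouse RNA lacks, read between 1.73 and 2.82 at E12.5, between 1.56 and 2.55 at P0, and between 1.47 and 2.64 at P5. For a gene whose dimmer group lies at that level, the size of the difference depends on the background correction.

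En1 (Entrez gene 13798), the gene that drives the V1 sort, was higher in V1 at every age. Its log2 expression at E12.5 was 8.20 ± 0.47 in V1 (SD, n = 3) and 3.16 ± 0.07 in dI4 (SD, n = 3), a log2 difference of 5.03. The log2 difference was 6.21 at P0 and 7.12 at P5, and every V1 array lay above every dI4 array. In dI4 at P0 En1 lay at the level of the control probe sets. Ptf1a, which is transcribed only briefly in dI4 progenitors and early neurons, read between 2.04 and 2.26 on all 17 arrays. That is the level of the control probe sets, also in dI4 at E12.5, and the cause of the low reading was not tested. Ptf1a stayed under the expression filter and was not compared between the classes.

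The comparison of V1 with dI4 at E12.5 asks which genes separate the classes soon after they are born. Hoxd10 had the largest difference in favour of V1, with log2 expression of 12.59 ± 0.31 (SD, n = 3) against 4.47 ± 3.06 in dI4 (SD, n = 3), a log2 difference of 8.12 ± 1.02 (SE, adjusted p = 0.00029). The transcription factor genes Lmo3, Nr5a2, Foxd3 and Otp followed, with log2 differences of 7.42, 6.48, 6.10 and 5.92. Pcp4, a calmodulin regulator, was higher in V1 by 5.68, the transporter gene Slc6a17 by 5.46 and the cadherin gene Cdh7 by 5.39. In the other direction the dorsal horn determinants Lbx1 and Tfap2b had log2 differences of −6.50 ± 0.31 (SE, adjusted p = 8.61e-08) and −6.34 ± 0.70 (SE, adjusted p = 0.000111). Nrn1, Skor1, Vgll3, Tfap2a, Pou4f1 and the mitotic gene Cenpf were lower in V1, with log2 differences from −5.62 to −5.08. For all 16 of these genes the V1 and dI4 arrays did not overlap, as the selection required. Nr5a2 and Slc6a17 in dI4 and Lbx1 in V1 lay at the level of the control probe sets.

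Of 20 tested V1 subset transcription factors, which mark molecular subsets of V1 neurons, 15 were higher and 2 lower in V1 at E12.5, and the same numbers were reached adjusted over the list alone. Foxp2 was higher by 5.06, while Nr2f2 and Prox1 were lower, with log2 differences of −3.56 and −1.42. Zfhx4 at 0.56 and St18 at 0.45 did not pass. The list's median log2 difference was 3.33 (camera, adjusted p = 1.61e-16), and the study chose this list on these samples, so it is not independent evidence. Of 7 tested genes of the dI4 lineage, 5 were lower and none higher in V1, and 6 were lower adjusted over the list alone. Gbx1 was lower in V1, at −4.51, whereas Gbx2 at −1.08 and Pax8 at −0.61 did not pass, and the list's median was −4.51 (camera, adjusted p = 9.33e-10).

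**Figure D1:**
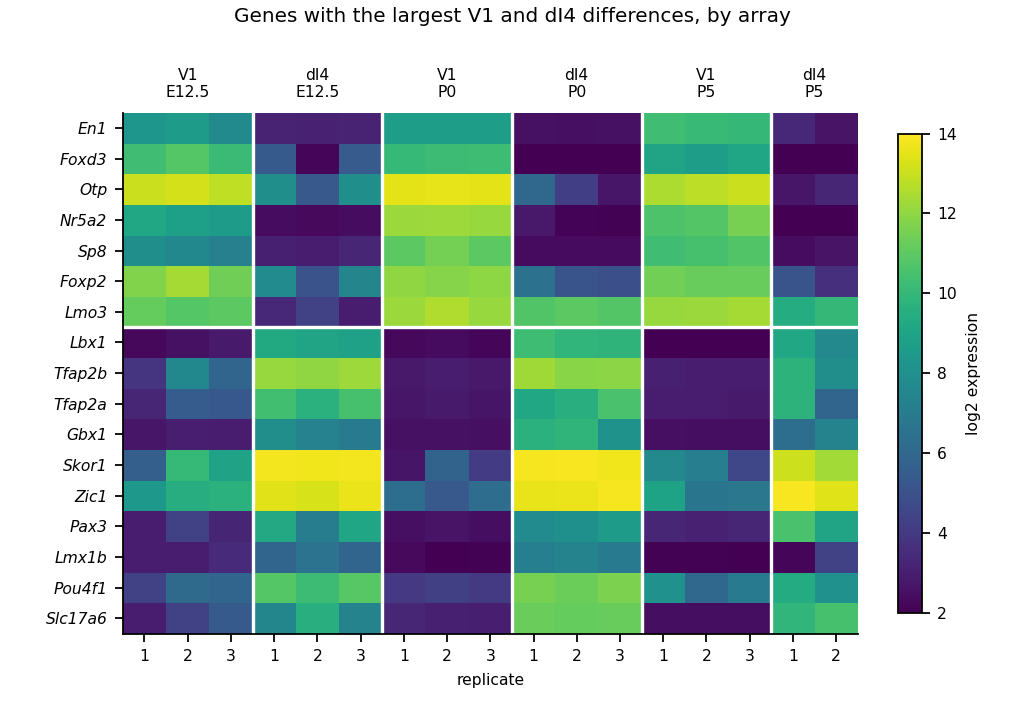
Log2 expression of En1, 6 other genes higher in V1 and 10 genes higher in dI4 on each of the 17 arrays, with groups side by side and replicates numbered. En1 lay between 7.69 and 10.34 on the V1 arrays and between 2.48 and 3.39 on the dI4 arrays.

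Both classes carried the GABA machinery at E12.5. Gad2 read 12.96 ± 0.05 in dI4 (SD, n = 3) and was lower in V1, with a log2 difference of −0.96, while Gad1 was higher in V1 by 0.93. The vesicular transporter gene Slc32a1 at 0.51 did not pass. Some excitatory markers were higher in the dI4 sort. Of 14 listed, 5 were tested, and 3 of these were lower and none higher in V1. Adjusted over the list alone 3 were lower and 1 higher. Tlx3 stayed under the expression filter and read between 1.87 and 2.12 on all 17 arrays. Pou4f1, Slc17a6 and Lmx1b had log2 differences of −5.17, −3.94 and −2.98, while Evx1 at 0.84 and Sim1 at −0.14 did not pass. Slc17a6 encodes the vesicular glutamate transporter VGLUT2, and it read 8.15 ± 1.23 in dI4 (SD, n = 3) against 4.20 ± 1.26 in V1 (SD, n = 3). The list's median was −2.98 (camera, adjusted p = 0.000616; adjusted p = 0.0608 with an estimated correlation). Among dorsal horn inhibitory subset markers, Npy and Sall3 were lower in V1, at −4.03 and −3.28, and the other 7 did not pass, with Rorb at −1.44 and Nos1 at 0.99. The Renshaw cell marker Calb1 was higher in V1 by 4.09.

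Many synaptic and receptor genes were higher in V1 at E12.5, whereas of 13 voltage-gated channel genes of mature neurons only Kcnc1 was, by 2.09, with a list median of 0.19 (camera, adjusted p = 0.195). That median was 0.06 without V1 replicate 3, 0.11 without dI4 replicate 3 and 0.25 without dI4 replicate 2, where the list was called (adjusted p = 0.041). Of 16 tested synaptic vesicle genes 8 were higher in V1 and none lower, with Sv2b at 4.61 ± 0.25 (SE) and Cplx1 at 1.97, while Snap25 at 0.13 did not pass, and 9 were higher adjusted over the list alone. The list's median was 0.63 (camera, adjusted p = 2.28e-06; adjusted p = 0.17 with an estimated correlation). Of 16 GABA and glycine receptor and chloride transporter genes 7 were higher and none lower, with Gabra5 at 3.34 and the chloride exporter Slc12a5 at 1.99, and 9 were higher adjusted over the list alone. The list's median was 0.82 (camera, adjusted p = 2.28e-06; adjusted p = 0.193 with an estimated correlation), and 1.24 without dI4 replicate 2. Among 13 glutamate receptor genes 5 were higher, including Grin2d at 2.83 and Gria4 at 1.62, and 6 were higher and 2 lower adjusted over the list alone. Of 26 axon guidance genes 10 were higher and 6 lower, with Sema3c at 5.23 and Nrp2 at 2.62 and with Robo3 at −3.88, and 12 were higher and 6 lower adjusted over the list alone. Of 14 progenitor and cell cycle genes 3 were lower in V1, Sox2 at −4.28, Mki67 at −2.54 and Ccna2 at −2.43, and 6 were lower adjusted over the list alone. That list's median was −1.77 (camera, adjusted p = 1.12e-06; adjusted p = 0.258 with an estimated correlation).

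Hox genes, which record position along the cord, differed between the classes at E12.5. Of 10 tested genes of paralogs 9 to 13, 6 were higher and 1 lower in V1, with Hoxd10 at 8.12, Hoxc10 at 4.34 and Hoxd9 at 3.42, and with Hoxb9 at −3.84. Adjusted over the list alone 7 were higher and 1 lower, and the median was 2.12 (camera, adjusted p = 0.000252; adjusted p = 0.17 with an estimated correlation). Of 11 genes of paralogs 4 to 8, 2 were higher and 4 lower, and 2 were higher and 5 lower adjusted over the list alone. Hoxb4, Hoxb6, Hoxb5 and Hoxb7 were the 4 lower genes, at −2.59, −2.25, −1.98 and −1.45, and Hoxc4 at −0.18 did not pass. Grouped by cluster, all 5 tested HoxB genes were lower at E12.5, with a median of −2.25, and all 4 HoxD genes were higher, with a median of 3.08. HoxA and HoxC genes went both ways, 1 of 5 and 3 of 7 being called higher and none lower, with values from −1.81 to 2.17 and from −0.18 to 4.34. At P0 none of the 4 HoxD genes passed, and they lay between −0.34 and 1.23, and at P5, 2 were higher and 1 lower. Of the HoxB genes 3 were lower at P0 and 2 at P5, and none was higher. The grouping by cluster was made after the values were seen. The tested HoxB genes were mostly of lower paralog number than the HoxD genes. Beyond Hoxb9 against Hoxd9, a difference by cluster cannot be told apart from a difference by paralog number for these genes.

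**Figure D2:**
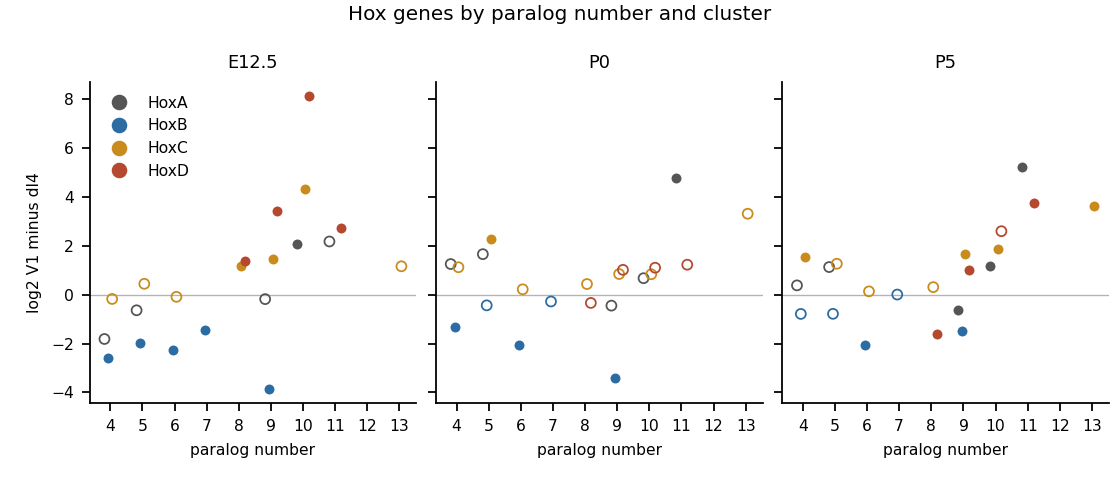
Log2 difference, V1 minus dI4, of each tested Hox gene against its paralog number at each age, with colour for the cluster and filled points for genes past the threshold. At E12.5 HoxB genes lay between −3.84 and −1.45 and HoxD genes between 1.39 and 8.12.

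In the limma test 1241 genes passed at E12.5, of which 912 were higher in V1 and 329 lower, and 543 and 223 of these differed at least 2-fold. Fitted on the E12.5 arrays alone, 397 genes passed, and Hoxd10, Skor1, Slc17a6 and Sox2 were no longer among them. Without V1 replicate 1 or 3, 671 or 751 genes passed, and without dI4 replicate 1 or 3, 718 or 733. The calls for Cenpf, Ccna2, Mki67 and Hoxb5 were lost without each of these 4 arrays, where their log2 differences lay between −5.07 and −4.36, −2.34 and −1.93, −2.58 and −2.05, and −1.93 and −1.85. Those for Cenpf and Ccna2 were also lost without V1 replicate 2, at −5.14 and −2.67, and without most arrays of the other ages, and that for Hoxb7 without V1 replicate 1, at −1.30. Without dI4 replicate 2, the dI4 array on which Hoxd10 was highest, 1920 genes passed, and the Hoxd10 difference was 9.88.

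At P0 the comparison asks how the classes differ as newborn circuits form. Nr5a2 had log2 expression of 12.21 ± 0.07 in V1 (SD, n = 2) and 2.34 ± 0.41 in dI4 (SD, n = 3), a log2 difference of 9.88 ± 0.27 (SE, adjusted p = 5.71e-10). Otp followed at 9.24 ± 0.85 (SE, adjusted p = 2.05e-05), then Sp8 at 8.88, Foxd3 at 8.21, the synuclein gene Sncg at 7.27, Cyp1b1 at 6.77 and Onecut2 at 6.57. Skor1, a corepressor gene of Lbx1-lineage neurons, was lower in V1, at −9.21 ± 1.15 (SE, adjusted p = 0.000242), as was Tfap2b, at −9.16. Slc17a6 at −8.11, Zic1 at −7.87, Vcam1 at −7.74 and Lbx1 at −7.69 were next. The astrocyte genes Gfap and Slc1a3 completed this group, at −7.68 and −7.67. Arrays of the classes did not overlap for any of these 15 genes, as the selection required. Nr5a2, Sp8 and Foxd3 in dI4, and Vcam1 and Lbx1 in V1, lay at the level of the control probe sets.

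Of the V1 subset transcription factors 16 were higher and 1 lower in V1 at P0, and 17 and 1 adjusted over the list alone, with Bhlhe22 at −0.11 and Prdm8 at 1.29 among those that did not pass. The median was 2.21 (camera, adjusted p = 1.55e-16). In the dI4 lineage list 4 genes were lower, Tfap2b, Lbx1, Tfap2a and Gbx1, and 5 adjusted over the list alone, with a median of −6.70 (camera, adjusted p = 2.29e-08). Pax8 at −1.64 and Gbx2 at −0.20 did not pass. Of 9 dorsal horn inhibitory subset markers 6 were lower and 2 higher in V1, and 7 and 2 adjusted over the list alone. Sall3, Rorb and Pdyn were at −5.14, −4.36 and −3.12 and Nos1 at 4.48, with a median of −2.41 (camera, adjusted p = 0.000924; adjusted p = 0.169 with an estimated correlation). Among excitatory markers Slc17a6, Pou4f1 at −7.35 and Lmx1b at −5.09 were lower in V1 and Evx1 at 2.67 was higher, the same numbers adjusted over the list alone. That median was −5.09 (camera, adjusted p = 0.0128; adjusted p = 0.169 with an estimated correlation). With no filter on dim probe sets it was 0.01.

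Gad2 did not differ detectably at P0, at 14.47 ± 0.03 in V1 (SD, n = 2) and 14.30 ± 0.09 in dI4 (SD, n = 3). The glycine transporter gene Slc6a5 was higher in V1 by 1.56, and Lhx1 was lower, at −2.17. Of 16 synaptic vesicle genes 5 were higher, among them Sv2b at 1.64, and 8 adjusted over the list alone, with a median of 0.68 (camera, adjusted p = 0.00016; adjusted p = 0.172 with an estimated correlation). Of 14 progenitor and cell cycle genes 5 were lower, among them Sox2 at −6.87 and Vim at −3.12, and 5 adjusted over the list alone. That median was −1.91 (camera, adjusted p = 8.75e-06; adjusted p = 0.241 with an estimated correlation), and −0.86 without dI4 replicate 3. Among axon guidance genes Sema3a at 2.55, Unc5a at 2.19 and Sema3c at 1.94 were among 6 higher genes, and Nrp1 at −1.74 was the 1 lower gene. Adjusted over the list alone 8 were higher and 3 lower. Hoxb9 at −3.42 and Hoxb6 at −2.04 were again lower in V1, and Hoxa11 was higher by 4.78.

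Glial markers were lower in V1 than in dI4 at P0. Gfap read 3.43 ± 1.10 in V1 (SD, n = 2) and 11.11 ± 0.29 in dI4 (SD, n = 3). Of 8 astrocyte markers 6 were lower and none higher, including the water channel gene Aqp4 at −5.66, and the count was 6 adjusted over the list alone. Aldoc at 0.18 and S100b at −0.98 did not pass, and the median was −4.33 (camera, adjusted p = 2.29e-08; adjusted p = 0.0944 with an estimated correlation). Of 12 oligodendrocyte lineage markers 3 were lower, Olig1 at −6.79, Olig2 at −3.85 and Pdgfra at −3.77, and 3 adjusted over the list alone. Mbp at −0.96 did not pass, and the median was −1.23 (camera, adjusted p = 0.000165; adjusted p = 0.169 with an estimated correlation). The oligodendrocyte median was −0.58 without V1 replicate 2 and −1.85 without the averaged V1 replicates 1 and 3. None of 7 microglial markers passed, and their median was −0.75, which became 0.12 without dI4 replicate 3. Csf1r read 12.51 on that array and 8.55 on the lowest dI4 array. Of 9 dissociation-linked immediate early and stress genes 5 were lower in V1, among them Fosb at −4.28 and Egr1 at −2.91. Adjusted over the list alone 6 were lower and 1 higher. The list's median was −2.42 (camera, adjusted p = 0.00217; adjusted p = 0.171 with an estimated correlation). A difference in dissociation between the sorts was not tested and cannot be told apart from a class difference in these genes.

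In the limma test 1393 genes passed at P0, with 650 higher (46.7%, and 68.2% when each array was centred on its median) and 743 lower in V1, and 437 and 588 differed at least 2-fold. Without V1 replicate 2, which leaves 1 V1 sample, 857 passed, and without the averaged V1 replicates 1 and 3, 582 passed. Without the latter the calls for Rorb, Lhx1, Vim, Nrp1, Fosb and Egr1 were lost, at −4.26, −1.99, −3.15, −1.67, −3.75 and −2.37. Without V1 replicate 2 those for Rorb, Vim and Nrp1 were lost, at −4.45, −3.08 and −1.82. Rorb was also not called without dI4 replicate 2, at −4.16, and Nrp1 without dI4 replicate 1 or 2, at −1.61 or −1.76. A lone V1 sample was assumed to vary like the other groups.

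**Figure D3:**
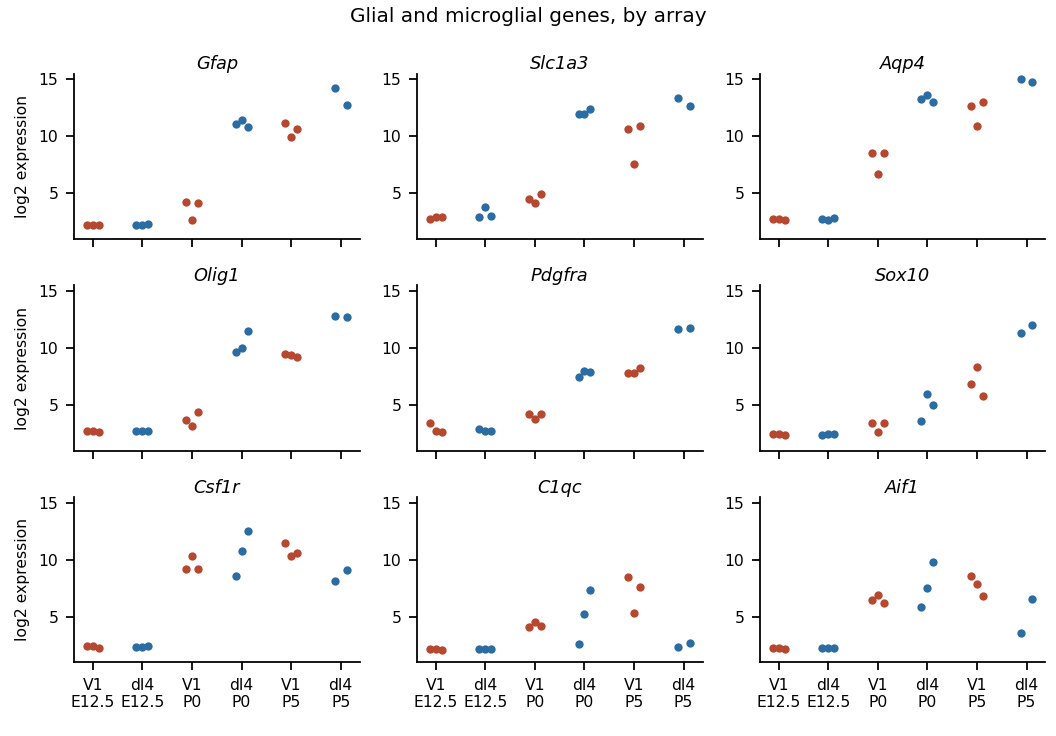
Log2 expression of 3 astrocyte genes (top), 3 oligodendrocyte lineage genes (middle) and 3 microglial genes (bottom) on every array, with V1 in red and dI4 in blue. At P5 Gfap lay between 9.91 and 11.17 in V1 and between 12.72 and 14.26 in dI4, while Csf1r lay between 10.35 and 11.48 in V1 and between 8.15 and 9.07 in dI4.

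At P5 the comparison asks which differences are present after birth. Otp had log2 expression of 12.80 ± 0.27 in V1 (SD, n = 3) and 2.99 ± 0.40 in dI4 (SD, n = 2), a log2 difference of 9.81 ± 0.85 (SE, adjusted p = 4.66e-06). Nr5a2 at 9.13, Sp8 (10.52 in V1 against 2.52 in dI4), Sncg at 7.95, the serotonin receptor gene Htr1b at 7.60, Cyp1b1 at 7.25 and Foxd3 at 7.20 were also higher in V1. Slc17a6 had the largest difference in favour of dI4, −7.76 ± 0.67 (SE, adjusted p = 4.61e-06), with 2.44 ± 0.02 in V1 (SD, n = 3) and 10.21 ± 0.44 in dI4 (SD, n = 2). Calcrl at −6.94, Lcat at −6.65, the dorsal neural tube gene Pax3 at −6.56 and Lbx1 at −6.38 followed, with Cldn10, Skor1 and Zic1 at −6.28, −6.26 and −6.19. No V1 array overlapped a dI4 array for these 15 genes, as the selection required. Nr5a2, Sp8, Sncg and Foxd3 in dI4, and Slc17a6 and Lbx1 in V1, lay at the level of the control probe sets.

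Of the V1 subset transcription factors 15 were higher and 1 lower in V1 at P5, and 17 and 1 adjusted over the list alone, with a median of 3.21 (camera, adjusted p = 4e-09). Of the dI4 lineage genes 5 were lower, and 5 adjusted over the list alone, with a median of −4.39 (camera, adjusted p = 0.00295; adjusted p = 0.184 with an estimated correlation). Pax8 at 0.58 and Gbx2 at −0.11 did not pass. Among dorsal horn inhibitory subset markers 7 were lower and 1 higher, and 7 and 2 adjusted over the list alone. Nos1 was higher by 5.75 and Sall3 and Rorb were lower, at −4.21 and −3.84, with a median of −1.55 (camera, adjusted p = 0.0374; adjusted p = 0.407 with an estimated correlation). The camera call was lost without V1 replicate 2 or 3 or dI4 replicate 2, where the medians were −1.54, −1.37 and −1.24. Slc6a5 and Slc32a1 were higher in V1 by 2.74 and 1.30, while Gad1 at 0.21 did not pass.

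Synaptic and channel genes were higher in V1 at P5. Of 16 synaptic vesicle genes 12 were higher and none lower, and 13 adjusted over the list alone, with Vamp1 at 2.64 ± 0.47 (SE, adjusted p = 0.000851), Syt2 at 2.18 and Rab3a at 1.95. Syp at 0.58 and Syt1 at 0.45 did not pass, and the median was 1.53 (camera, adjusted p = 4.58e-06; adjusted p = 0.184 with an estimated correlation). Of 13 voltage-gated channel genes of mature neurons 9 were higher and none lower, the same number adjusted over the list alone, with Hcn2 at 3.23 and Scn1a at 1.87. Their median was 1.61 (camera, adjusted p = 0.000175; adjusted p = 0.184 with an estimated correlation). The NMDA receptor genes Grin2a and Grin1 were higher by 4.56 and 2.97. Among GABA and glycine receptor genes 7 were higher and 3 lower, the same adjusted over the list alone, with Gabrb2 at 2.12 and Glra1 at 2.07 and with Gabrg1 at −2.43. Of 26 axon guidance genes 12 were higher and 4 lower, the same adjusted over the list alone, with Unc5a at 6.29 and Sema3a at 4.36. Among 12 immature neuron genes 5 were higher, including Stmn2 at 1.31 and Tubb3 at 1.14, and Sox4 was lower at −1.28, but its probe sets disagreed, from −1.28 to 0.68. Adjusted over the list alone 5 were higher and 2 lower.

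Astrocyte and oligodendrocyte markers were lower in V1 at P5, and microglial markers were higher. Of 12 oligodendrocyte lineage markers 10 were lower and none higher, the same adjusted over the list alone, with Gpr17 at −5.70, Olig2 at −4.86, Cspg4 at −4.76 and Sox10 at −4.64. Mbp at −1.27 did not pass, and the median was −3.52 (camera, adjusted p = 7.71e-06; adjusted p = 0.184 with an estimated correlation). Of 8 astrocyte markers 6 were lower, and 7 adjusted over the list alone, with Fgfr3 at −3.75 and S100b at −3.25 and a median of −2.80 (camera, adjusted p = 0.00098; adjusted p = 0.288 with an estimated correlation). Of 7 microglial markers 5 were higher, and 6 adjusted over the list alone, with C1qc at 4.59, Aif1 at 2.64 and Csf1r at 2.20. Their median was 2.38 (camera, adjusted p = 0.0374; adjusted p = 0.551 with an estimated correlation), and the camera call was lost without V1 replicate 3 or dI4 replicate 1, where the medians were 2.30 and 1.74. The calls for Aif1 and Csf1r were lost without most single arrays, where Aif1 lay between 1.15 and 2.64 and Csf1r between 1.74 and 2.66. Of 14 progenitor and cell cycle genes 12 were lower, and 13 adjusted over the list alone, with Ccnb1 at −6.04 and Sox2 at −3.91 and a median of −2.80 (camera, adjusted p = 0.00014; adjusted p = 0.407 with an estimated correlation). Of 9 dissociation-linked immediate early and stress genes 6 were lower, with Fos at −3.16 and Egr1 at −2.75. The heat shock genes Hspa1a and Hspa1b were the 2 higher, at 2.03 and 2.10. The counts were the same adjusted over the list alone.

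Hoxb6 at −2.07 was lower in V1 at P5 as at the earlier ages. Of 10 Hox genes of paralogs 9 to 13, 7 were higher and 2 lower at P5, and 8 and 2 adjusted over the list alone, with Hoxa11 at 5.21 and Hoxd11 at 3.73. In the limma test 5219 genes passed at P5, with 2736 higher (52.4%, and 75.4% with centred arrays) and 2483 lower in V1, and 1602 and 1750 differed at least 2-fold. Fitted on the P5 arrays alone, where V1 replicates had the lowest correlations of any group, 2489 passed. Without dI4 replicate 1, which leaves 1 dI4 array, 3355 passed, and the calls for Rorb, Fos, Egr1 and Scn1a were lost, at −3.80, −2.91, −2.34 and 1.40.

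**Figure D4:**
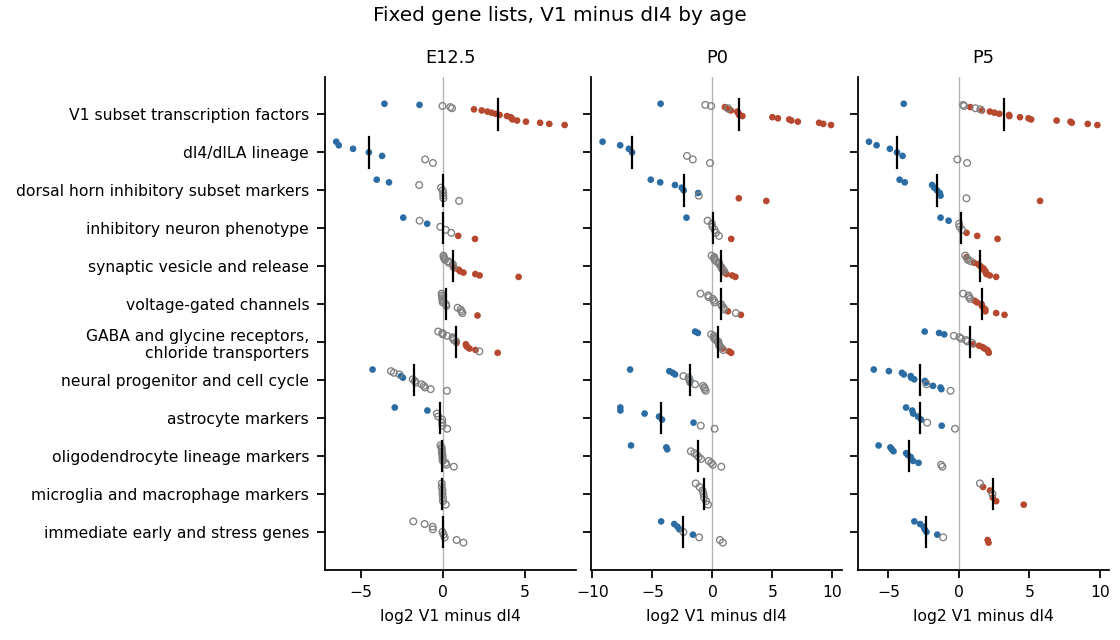
Log2 difference, V1 minus dI4, of the tested members of 12 fixed gene lists at each age. Filled points passed the threshold, red higher and blue lower in V1, and bars mark medians, which were 1.53 for synaptic vesicle genes and −3.52 for oligodendrocyte lineage markers at P5.

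Some genes separated the classes at every age. Averaged over the 3 ages, Nr5a2 was higher in V1 by 8.50 ± 0.15 (SE, adjusted p = 2.97e-12), Otp by 8.32, Foxd3 by 7.17, Sp8 by 7.13 and Foxp2 by 6.13. Tfap2b was lower in V1, at −7.11 ± 0.44 (SE, adjusted p = 2.32e-07), as were Skor1 at −7.02, Lbx1 at −6.86, Slc17a6 at −6.61 and Zic1 at −6.12. The arrays of the classes did not overlap at any age for these 10 genes, as the selection required. In the limma test 5742 genes passed for this mean, 3264 higher (56.8%, and 77.0% with centred arrays) and 2478 lower in V1, and 791 and 991 differed at least 2-fold. At all 3 ages 112 genes were higher in V1, where 9.75 would be shared if the ages were independent, and 111 were lower, where 3.65 would be. The fit gave each gene the same spread at every age, so calls are not independent between ages. An excess over 9.75 or 3.65 therefore does not by itself measure class differences shared by the ages. Between P0 and P5, 482 higher and 609 lower genes were shared and 10 were called in opposite directions. Between E12.5 and P5, 62 genes were called in opposite directions, where independence would give 245.3, a number with the same limit.

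The difference between V1 and dI4 was itself compared between ages, each age against its own dI4 arrays because the ages look normalized separately. A different scale of values at each age would still enter these changes. From E12.5 to P0 it rose for the detoxifying enzyme gene Cyp1b1 by 6.79 ± 0.37 (SE, adjusted p = 1.84e-06), the signalling adaptor gene Irs4 by 6.28 and Sncg by 6.23. Cyp1b1 read 2.72 in V1 and 2.74 in dI4 at E12.5, and 10.15 and 3.38 at P0. The difference fell for the matrix genes Nid1 and Tnc, with changes of −7.77 and −7.43, and for Gfap, with −7.65. From P0 to P5 it rose for Pou4f1 by 5.64 ± 0.85 (SE, adjusted p = 0.00287), from −7.35 to −1.72. It also rose for Gfap, by 4.78, and for the secreted phosphoprotein gene Spp1, by 5.13 (SE 1.33, adjusted p = 0.0424), whose call was lost when most single arrays were left out, with values between 4.27 and 5.31 there. The difference fell for Bmp4, Gjc3 and Lims2, with changes of −5.83, −5.69 and −5.46. These genes lay at the level of the control probe sets in both classes at P0 and read 9.67, 9.43 and 9.60 in dI4 at P5. In the limma test 546 genes passed from E12.5 to P0, 161 rising (29.5%, and 41.7% with centred arrays) and 385 falling, and 757 from P0 to P5, 385 rising (50.9%, and 67.1% with centred arrays) and 372 falling. Without dI4 replicate 2 at E12.5 the first count was 1017. Without the averaged V1 replicates 1 and 3 at P0 the counts were 294 and 350, and without V1 replicate 2 at P0 they were 349 and 290. Without dI4 replicate 1 or 2 at P0 the second count was 502 or 417.

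Gene families defined by symbol were compared with all other tested genes by Fisher's exact test, two-sided, over 24 tests. Transcription factor families were over-represented among genes lower in V1 at every age, and among genes higher in V1 at E12.5 and P0. At E12.5, 56 of 301 were lower (18.6%, against 2.2% of other genes, odds ratio 10.3, adjusted p = 2.27e-31), with Lbx1, Tfap2b and Pou4f1 among the genes named above, and 33 were higher (odds ratio 1.64, adjusted p = 0.0216). At P0, 72 were lower (23.9% against 5.3%, odds ratio 5.59), among them Zic1 and Zic2 at −7.87 and −7.57, and 28 were higher (odds ratio 1.98, adjusted p = 0.00404). At P5, 100 were lower (odds ratio 2.13, adjusted p = 4.63e-08) and 52 higher (odds ratio 0.771, adjusted p = 0.121). With no filter on dim probe sets the odds ratio for the higher genes at P5 was 0.707 (adjusted p = 0.0162). Neurotransmitter receptor families were over-represented among genes higher in V1: 15, 17 and 35 of 69 members at E12.5, P0 and P5, with odds ratios of 3.70, 6.30 and 3.86. At P0 these included Htr1b at 5.65 and Htr4 at 2.20. Cell adhesion and axon guidance families had 35 of 142 members higher at E12.5 (odds ratio 4.43, adjusted p = 3.2e-10) and 11 lower (odds ratio 3.29, adjusted p = 0.00246). They had 17 and 45 members higher at P0 and P5 (odds ratios 2.61 and 1.74, adjusted p = 0.0021 and adjusted p = 0.00723). Of ion channel families 13 of 110 members were higher at E12.5 (odds ratio 1.77, adjusted p = 0.0839), with an odds ratio of 2.83 at 2-fold (adjusted p = 0.00386). Ion channel families had 12 of 110 members higher at P0 (odds ratio 2.33, adjusted p = 0.0216; 2.03, adjusted p = 0.0545 with no filter on dim probe sets) and 43 at P5 (odds ratio 2.41, adjusted p = 6.14e-05). At P0 the potassium channel genes Kcnj16 and Kcnj10, at −6.30 and −5.59, were among 11 lower members (odds ratio 1.83, adjusted p = 0.0839; 2.35, adjusted p = 0.0261 among genes that differed at least 2-fold). At P5 12 members were lower (odds ratio 0.511, adjusted p = 0.0419; 0.706, adjusted p = 0.414 at 2-fold).

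The authors' deposited table gave En1 fold differences of V1 over dI4 of 32.8, 74.3 and 139 at the 3 ages. Across all 45101 probe sets the authors' folds, on the log2 scale, and the differences between group means had a correlation of 1 at each age. That table's unadjusted p-values were under the 0.05 threshold for 5662, 9677 and 12661 probe sets, and after Benjamini-Hochberg adjustment for 16, 2621 and 502. At P0 those p-values match a test that counts V1 replicates 1 and 3 as separate samples, unlike the fit here. The P0 count is therefore not comparable with those at the other ages.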

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

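The tests of explanations and of other splits in this part were chosen only after the results were seen, while the comparison of the V1 minus dI4 difference between ages was planned.

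Results here were picked out because the difference between V1 and dI4 itself changed between ages in the limma test. From E12.5 to P0 the change was 6.79 for Cyp1b1, 6.28 for Irs4 and 6.23 for Sncg, and −7.77 for Nid1, −7.65 for Gfap and −7.43 for Tnc. From P0 to P5 it was 5.64 for Pou4f1, 5.13 for Spp1 and 4.78 for Gfap, and −5.83 for Bmp4, −5.69 for Gjc3 and −5.46 for Lims2. The Spp1 call was lost without most single arrays, where its value lay between 4.27 and 5.31. These are the 3 highest and 3 lowest called genes per comparison, so their sizes are the extremes of many. They also carry any difference in scale between the ages.

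Called astrocyte and oligodendrocyte lineage markers were all lower in V1 than in dI4 at P0 (6 of 8 and 3 of 12) and P5 (6 of 8 and 10 of 12), but the camera calls were lost with an estimated correlation (adjusted p = 0.0944 and adjusted p = 0.169 at P0, adjusted p = 0.288 and adjusted p = 0.184 at P5). A single array as the cause is argued against, since the list medians stayed below 0 without each array: at or below −4.21 and −2.15 for astrocyte markers at P0 and P5, and at or below −0.58 (without V1 replicate 2 at P0) and −3.21 for oligodendrocyte markers. If a lower share of neurons in the dI4 sorts raised every other cell type there alike, microglial markers would be lower in V1 too. At P5 the microglial median was 2.38 in favour of V1, and between 1.74 and 2.66 without each array. Its camera call was lost without V1 replicate 3 or dI4 replicate 1 and with an estimated correlation (adjusted p = 0.551), and the calls for Aif1 and Csf1r without most single arrays. These values argue only against such a uniform rise as the whole cause at P5. A lower neuron share with some cell types carried along more than others was not tested. At P0 the microglial median was −0.75, with no member called, and 0.12 without dI4 replicate 3, so a lower neuron share and a glial difference alone cannot be told apart there. Glia marked by Ptf1a-Cre, glia carried along in the dI4 sort, and glial genes expressed in the dI4 neurons themselves stay open and untested. The V1 arrays at P5 held glial transcripts too, with Gfap between 9.91 and 11.17 and Mbp between 13.67 and 14.84. Their source was not tested.

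Of 10 tested Hox genes of paralogs 9 to 13, 6 were higher and 1 lower in V1 at E12.5, with a list median of 2.12. The camera call was lost with an estimated correlation (adjusted p = 0.17). A single array is argued against, since the median stayed at or above 1.80 without each array. Cords taken at different levels for the 2 lines would move members of 1 paralog group together, and Hoxb9 was at −3.84 beside Hoxd9 at 3.42, but 1 gene decides nothing for the set. A difference in level and a difference between the classes cannot be told apart for this list, because every V1 array came from 1 line and every dI4 array from the other. A class difference in Hox use at E12.5 stays open, untested, and at the later ages HoxD genes lay in both directions, with none of 4 called at P0 and 2 higher and 1 lower in V1 at P5.

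Synaptic vesicle genes were higher in V1 at P5, with a list median of 1.53, but the camera call was lost with an estimated correlation. Fewer neurons in the dI4 sorts would lower the genes of the inhibitory phenotype in dI4 as well, and their median was 0.13, with members in both directions, which decides nothing. Later maturation of the dI4 cells would raise immature neuron genes there, and their median was 0.28 in favour of V1, with members in both directions, and −0.09 without dI4 replicate 2. Neither can be told apart from a difference between the classes, which the design names and which was not tested separately.

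Other splits of the same arrays were also compared with the real grouping. Within an age only 10 splits exist, too few for a share under 0.05: the real grouping called 1241 genes at E12.5 against at most 9 in the others, 1393 at P0 against at most 31, and 5219 at P5 against at most 741, so that 1 split, the real one, reached each count. For the mean over ages, 1 of 100 splits, the real one, called as many as 5742 genes, with 3278 the highest of the others. The 100 splits drawn of 2000 cannot give a share under 1 in 100. Chance in the grouping was therefore not excluded, only bounded by that share. Every V1 array came from 1 line and every dI4 array from the other, so the splits cannot separate class from line.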

How the results depend on the processing

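Of the alternatives below, 3 were chosen after seeing the data: V1 replicates 1 and 3 at P0 entered separately, the arrays least like their own group at E12.5 and at P0 left out together, and V1 at P5 left out of the shared spread.

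Counts of called genes stayed within 1.5 times the reported count in 142 of 181 alternatives. Array weights raised them to 3064 at E12.5, 3703 at P0, 2618 for the change from E12.5 to P0 and 1258 for that from P0 to P5. Fitting only the groups compared gave 397 at E12.5, 2489 at P5, and 904 and 351 for the 2 changes. Entering V1 replicates 1 and 3 at P0 separately gave 2341 at P0, and 898 and 1212 for the changes. Without the 2 doubted arrays (dI4 replicate 2 at E12.5 and dI4 replicate 3 at P0) the counts were 2022 at E12.5 and 1113 for the first change. The upper-quartile filter gave 912 at P0 and 379 for the second change. For these the cause was not tested. Stricter thresholds lower counts by construction: at least 2-fold gave 766 at E12.5, 3352 at P5 and 1782 for the mean over ages, and an adjusted p under 0.01 gave 594, 722, 3412, 3788, 245 and 244 at E12.5, P0, P5, for the mean and for the 2 changes.

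Leaving out 1 array at a time, counts ranged from 671 (without V1 replicate 1) to 1920 (without dI4 replicate 2) at E12.5, from 582 (without the averaged V1 replicates 1 and 3) to 1629 at P0, and from 3355 (without dI4 replicate 1) to 5326 at P5. They ranged from 4747 to 5901 for the mean, from 294 (without the averaged V1 replicates at P0) to 1017 (without dI4 replicate 2 at E12.5) for the first change and from 290 (without V1 replicate 2 at P0) to 1051 for the second.

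Some list medians changed sign, and the cause was not tested. Dorsal horn inhibitory markers at E12.5, at −0.02, were at 0.002 with the upper-quartile filter, 0.047 quantile normalized again, 0.025 median centred and 0.025 without the 2 doubted arrays, and ranged from −0.032 to 0.025 (without dI4 replicate 2) with 1 array left out. With no filter on dim probe sets, excitatory markers were at 0.012 at P0 and 0.039 at P5, Hox paralogs 4 to 8 at −0.001 at P0 and endothelial markers at 0.10 at P5. Microglial markers at P0 were at 0.12 without the 2 doubted arrays and ranged from −1.86 to 0.12 (without dI4 replicate 3), endothelial markers at E12.5 from −0.035 (without V1 replicate 1) to 0.25, and immature neuron genes at P5 from −0.086 (without dI4 replicate 2) to 0.36. Sox4 at P5 was at 0.023 as the mean of its probe sets, which disagreed. At 2-fold, odds ratios moved across 1 for transcription factor families among higher genes at P5 (1.08), and for receptor and adhesion families among lower genes at P0 (0.95 and 0.92).

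Across list medians, 1344 of 1469 alternatives kept direction and side of the threshold, 77 lost a camera call and 35 gained one; the estimated correlation accounted for 27 of the losses. For named genes 6551 of 7015 kept both and 463 lost a call, 42 of them without the averaged V1 replicates at P0 and 47 when only the groups compared were fitted. For families 39 of 48 kept both, 3 gained and 3 lost a call.

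With the replicate number as a block the counts were 1193, 1251, 5125, 5714, 481 and 545, and 3 list calls and 13 named-gene calls were lost. Same-number arrays of the 2 classes had correlations between −0.19 and 0.14, and different-number arrays between −0.14 and 0.14, so the numbers were not read as pairs.

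Centring each array on its median moved the median difference of all genes by 0.18 at P0, 0.34 at P5 and 0.19 for the mean, and by 0.14 and 0.16 for the 2 changes. The share of called genes that were higher in V1 went from 46.7% to 68.2% at P0, 52.4% to 75.4% at P5 and 56.8% to 77.0% for the mean, and the rising share from 29.5% to 41.7% and 50.9% to 67.1% for the changes. Array weights took it from 73.5% to 62.9% at E12.5. Families were run only with no filter and at 2-fold, the mean over ages has no fit of only the groups compared, and changes between ages within a class were not run. Signal over background limits genes at the control level, where 1523 tested genes lay in both classes at E12.5.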

Other observations

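No test in this part was chosen only after the result was seen; the gene lists and their tests were planned.

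Voltage-gated channel genes of mature neurons were compared at P0 and between ages as well. The change in the difference had a median of 1.04 from P0 to P5 (camera, adjusted p = 0.00145; adjusted p = 0.383 with an estimated correlation), with 3 members called, and did not pass from E12.5 to P0 (camera, adjusted p = 0.436). At P0 Kcna1 and Kcna2 were higher, by 2.37 and 1.29, and 5 adjusted over the list alone, with a median of 0.72 (camera, adjusted p = 0.0442; adjusted p = 0.44 with an estimated correlation). The camera call was lost without the averaged V1 replicates at P0 or without dI4 replicate 3 at P0, where the medians were 0.33 and 0.54, and without V1 replicate 3, dI4 replicate 1 or dI4 replicate 2 at E12.5 or V1 replicate 2 at P5, where it stayed 0.72. The calls for Kcna1 and Kcna2 were lost without the averaged V1 replicates (at 2.12 and 1.32) or V1 replicate 2 at P0 (at 2.62 and 1.26), and that for Kcna2 also without each dI4 array at P0, at 1.15 to 1.36, and each E12.5 array.

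Of the listed markers of motor neurons, red blood cells and peripheral sensory neurons, only 1 of 7, 1 of 9 and 2 of 8 were tested. Glial and microglial markers were not dim at P5, in V1 as well as in dI4. Mbp lay between 13.67 and 14.84 on the V1 arrays at P5, and higher on the dI4 arrays. Csf1r lay between 10.35 and 11.48 on the V1 arrays at P5, and lower on the dI4 arrays. Isl1 of motor neurons was the 1 tested gene of its list and did not pass, at −0.07, 1.33 and 0.55 at the 3 ages, and Hbb-y of red blood cells did not pass, at −1.18, 0.01 and 0.03. Of the sensory neuron genes Scn9a was higher in V1 by 1.05 at E12.5 and 0.90 at P5, with both calls lost without most single arrays, where it lay between 0.89 and 1.19 and between 0.38 and 0.97, and Calca did not pass. Of endothelial and mural genes Pdgfrb was lower in V1 at P0 and P5, at −3.03 and −1.85 (the P5 call was lost without dI4 replicate 1, at −1.36), and Flt1 was higher at P5, at 2.74. The endothelial list's median at P0 was −1.49 (camera, adjusted p = 0.0277; adjusted p = 0.171 with an estimated correlation), and −0.77 without the averaged V1 replicates. Of the Renshaw and Ia cell markers Pvalb was higher in V1 by 2.19 at P5, a call lost without V1 replicate 1 or 3 or either dI4 array, at 1.48 to 2.20, and Chrna2 did not pass at any age.

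Xist read 2.67 on dI4 replicate 2 at E12.5 and 2.58 on dI4 replicate 1 at P5, Kdm5d read 2.00, 2.26 and 2.27 on V1 replicate 2 at E12.5, dI4 replicate 1 at P0 and dI4 replicate 2 at P5, and the other arrays held both transcripts.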
